A study of Homo sapiens with 11 samples.

How the data were processed

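T-REx-293 is a derivative of the human embryonic kidney line HEK293 in which expression from a plasmid is switched on by tetracycline. Per the labels' protocols, cells carrying a plasmid for the green fluorescent protein (GFP) received 2.5 µg/mL tetracycline for 72 h and then expressed an empty vector, an shRNA against GFP, or 1 of 2 shRNAs against Tat-SF1, called shRNA A and shRNA B here. Total RNA was purified on columns and treated with DNase, labelled by the whole transcript sense target method, and hybridised to Affymetrix Human Exon 1.0 ST arrays. The series design describes 12 biological replicates, 3 per construct, of which replicate 3 of the empty vector failed quality control, so that 11 arrays were analysed here. The empty vector (2 arrays) and the GFP shRNA (3 arrays) formed the control group of 5 arrays, and shRNA A and shRNA B (3 arrays each) formed the knockdown group of 6.

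The deposited table holds log2 values of 1399022 exon probe sets on the 11 arrays. The software, background correction, normalization and genome build behind the values are not given in the sources used here. From the values, the scale is log2 and the values are not centred per gene. The array medians lie between 7.901 and 7.904 on the log2 scale, and dim probe sets crowd around this level, which is taken as a background here. It is not part of every value, since some probe sets lie well below it, such as 3555332 with a control mean of 4.56. A change of a gene near that level may therefore be compressed, and fold changes on this scale may understate the change of the transcript. No pair of arrays had the same distribution of values. Each array lacked an estimate for between 13190 and 15431 probe sets. The number of arrays limits the precision of every comparison.

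Probe sets were assigned to genes through a table of gene symbols for this array. Of the probe sets, 355799 carried 1 gene symbol, 15195 carried several and were not used for genes, and 1028028 were not listed there. Symbols were updated through the synonyms of the RefSeq annotation of GRCh38.p14. Of 19536 symbols, 16450 were current, 2893 were updated through a unique synonym and 193 were kept as they were. No coordinates are given because the build of the table is not named.

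A probe set entered the gene values if it had 1 symbol, an estimate on every array and a mean over the 11 arrays at or above the median of the whole table (7.91), and a gene needed at least 4 such probe sets. This left 221964 probe sets and 14579 genes, with a median of 12 probe sets per gene. The gene value on an array was the median of its probe sets. The splicing index, used for exon usage, was the probe set's log2 value minus the gene value on the same array. It shows unequal change within a gene and not which part of the gene changed.

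Differences were tested on the log2 scale with limma (lmFit and eBayes with a trend), and p-values were adjusted by the Benjamini-Hochberg method over all genes or all probe sets tested. All adjusted p-values below come from limma unless another test is named, and a gene or probe set passed with an adjusted p under 0.05. The pooled comparison used 2 levels, the comparisons of each shRNA with the control and with each other used 3 levels, and the comparison of the 2 control constructs used 4 levels, always over the 11 arrays. Single values were compared by exact two-sided permutation tests over all 462 splits of the 11 arrays, whose smallest possible p is 0.0022. Lists of genes, 27 of pathways and complexes and 5 of markers of other cell types, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. A list needed at least 5 measured genes, which left 31 lists. R 4.3.3, limma 3.58.1 and version 1.17.8 of the data.table package were used.

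The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named HTATSF1, then the 12 largest rises and the 12 largest falls among genes that passed and whose 6 knockdown arrays all lay on one side of all 5 controls. For exon usage it named up to 10 probe sets by the same conditions, 1 per gene. For a list it named up to 4 members that passed, or otherwise up to 2 with the largest change, given as values. For shRNA B against shRNA A and for the 2 controls it named up to 5 rises and 5 falls that passed. Genes named for shRNA A and shRNA B alone, the called genes beyond the 12 largest falls, and the genes that passed only after quantile normalization, were named after their values were seen.

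The tests were tried on simulated data, drawn from normal distributions with the means and the spreads within constructs of the real arrays. Of 200 changed genes among 14579, 78% were recovered at a log2 change of 0.25, 98% at 0.5 and 100% at 1, with 8, 9 and 11 other genes called. Of 200 changed probe sets among 221964, 64% were recovered by the splicing index at 0.5 and 96.5% at 1. At that larger change 26 other probe sets were called, 10 of them in the changed genes. A shift of -0.1 put into 1 list was called, with no other list called. The simulated genes and probe sets were drawn independently of each other, without a brightness shared within an array. On the real arrays the estimated correlation within a list was as high as 0.37, so these rates need not hold there.

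The alternatives were no filter or a higher floor for dim probe sets, quantile normalization, limma without a trend, the mean in place of the median, blocks for the replicate number or for a suffix in the array names, the constructs as levels or as a random block, other control arrays, a minimum of 1.5-fold, diffSplice for exon usage, and leaving out each array in turn. Alternatives added after seeing the data are named where they are used. The suffix is present on 4 arrays (shRNA A replicate 3 and the 3 of shRNA B), and its meaning is not given in the sources used here.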

Results

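The transcriptome of T-REx-293 cells was measured on 11 exon arrays to find genes and exons that change when Tat-SF1 is depleted. Tat-SF1, encoded by HTATSF1, is a cofactor of transcription elongation that also binds the U2 snRNP of the spliceosome. The control group held 2 empty vector and 3 GFP shRNA arrays, and the knockdown group held 3 arrays each of shRNA A and shRNA B. Across all probe sets with an estimate, the correlation between pairs of arrays lay between 0.941 and 0.962, and no pair stood out as a duplicate. The 3000 brightest genes of each array averaged 9.257 ± 0.0446 (SD, n = 6) in the knockdown arrays and 9.324 ± 0.0411 (SD, n = 5) in the controls, on the log2 scale (exact permutation p = 0.0303). The brightest array was GFP shRNA replicate 1, at 9.382, and the dimmest was shRNA B replicate 1, at 9.182. These arrays also lay at the 2 ends of the first principal component of the gene values, with scores of 11.67 and -8.64.

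HTATSF1 was lower with both shRNAs. Its gene value averaged 8.50 ± 0.12 (SD, n = 5) in the controls and 8.21 ± 0.057 (SD, n = 6) in the knockdown arrays, and every knockdown array lay below every control (exact permutation p = 0.0022, the smallest possible). All 14 of the probe sets used, of 17 on the array, had a lower mean in the knockdown arrays, by between -0.06 and -0.43. On the scale of signal above each array's median level, the gene had 125 ± 28.4 units (SD, n = 5) in the controls and 56.2 ± 11.7 units (SD, n = 6) in the knockdown arrays. If the median level is taken as background, this was 45.0% of the control signal, with 50.6% for shRNA A and 39.3% for shRNA B. The log2 difference of -0.30 had a standard error of 0.051 and passed the test over all genes narrowly, with an adjusted p of 0.0486. Its adjusted p lay between 0.0111 and 0.367 over the alternatives, and it was between 0.057 and 0.104 when any of 10 of the 11 arrays was left out (all except empty vector replicate 2, with 0.0166).

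**Figure D1:**
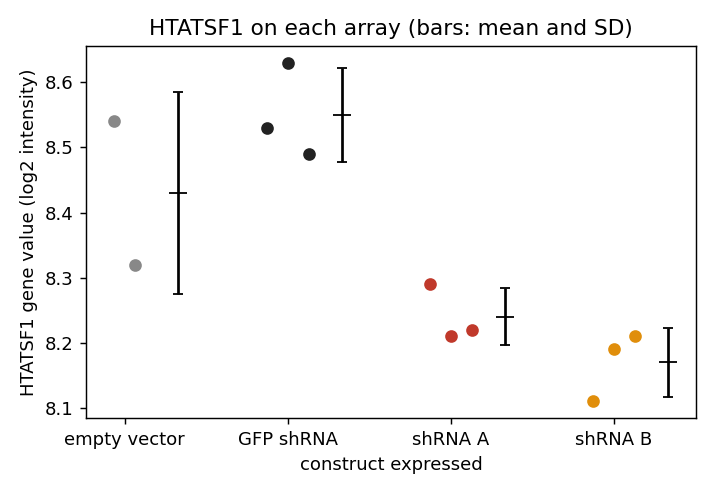
HTATSF1 gene value (log2 intensity, vertical axis) on each array, grouped by the construct expressed. Points are arrays and the bar beside each group is its mean with the SD; the highest knockdown array, at 8.29, lies below the lowest control, at 8.32.

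The first question of the design was which transcripts change on depletion. Among the 27 genes that fell were TMSB10, which binds actin monomers (-0.51, from 10.44 ± 0.13 to 9.92 ± 0.21), EEF1D, a subunit of a translation elongation factor (-0.44), APRT, an enzyme of adenine salvage (-0.43), and RAC3, a small GTPase (-0.43, from 9.81 ± 0.09 to 9.38 ± 0.03; SD, n = 5 controls and 6 knockdown arrays). NME3, a nucleoside diphosphate kinase, fell by 0.415 and STUB1, a ubiquitin ligase that works with chaperones, fell by 0.41. HMG20B, a subunit of a histone demethylase complex, fell by 0.38 and HDGF2 fell by 0.37. The 12 largest falls were completed by the receptor gene OGFR (-0.35), the actin gene ACTA2 (-0.34), the phosphatase subunit PPP4C (-0.33) and the prolyl isomerase FKBP1A (-0.32). The 5 genes that rose were CPNE7 (0.27), ONECUT1, which encodes a homeobox transcription factor (0.24), GRM4, a metabotropic glutamate receptor (0.20), TRIML2 (0.09) and CELF6, an RNA-binding protein (0.08).

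The other falls that passed included CCND1, a D-type cyclin (-0.27), the histone variant gene H2AX (-0.31), the histone-binding protein gene RBBP4 (-0.29), IGFBP2 (-0.31), UXT (-0.31) and NPTX2 (-0.26). In all, 32 of 14579 genes passed, 5 higher and 27 lower in the knockdown arrays, with the smallest adjusted p at 0.0171. The 27 falls include HTATSF1, the target of both shRNAs. None changed by 1.5-fold on this scale; TMSB10, the largest, was 1.43-fold lower. On a background-subtracted scale, chosen after seeing the data, the 27 falls had a median of -0.641 and the 5 rises one of 0.763, against -0.313 and 0.204 as deposited. That scale set signals below the array median to 0 and added a constant. All rises except ONECUT1 (8.57) had control means near that level, at 7.94 (TRIML2), 7.95 (CELF6), 8.05 (GRM4) and 8.13 (CPNE7). The size of the rises on it therefore rests on small signals. In each of the 32 genes the groups did not overlap. Over all genes, the groups did not overlap in 327 genes (2.24%, against 0.43% by chance), and 2216 genes had an unadjusted p under 0.05, against 729 by chance. Of the 32 genes, 8 had a control mean under 8.2, near the level of dim probe sets, and the probe sets of EEF1D and RBBP4 lay in 4 separate runs of probe set numbers, so their values come from several places in the numbering. The knockdown arrays were dimmer than the controls, as given above, and 4 of the 6 knockdown arrays but no control array had the suffix in their names.

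The number of genes was not stable: it lay between 0 and 279 over the alternatives, and leaving out 1 array gave 5, 4 and 3 (shRNA A replicates 1 to 3), 4, 4 and 7 (shRNA B), 8, 12 and 2 (GFP shRNA), 5 (empty vector replicate 1) and 47 (empty vector replicate 2). With the array-name suffix as a block no gene passed by limma (1282 at an unadjusted p under 0.05), none passed without the 2 arrays at the ends of the first component (1708, an alternative chosen after seeing the data), and after quantile normalization 8 genes passed, of which 6 were among the 32 (3 rises and 3 falls) and 2, BOLA2 (0.36) and CGGBP1 (0.25), were rises that had not passed before, so that the share of higher genes was 62.5% in place of 15.6% (71.4% with cyclic loess, also chosen after seeing the data).

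The sizes of many changes depended on which probe sets entered the gene value. Without the filter on dim probe sets all 5 rises were lost, with CPNE7 at 0.047, GRM4 at 0.011, TRIML2 at 0.012, ONECUT1 at -0.009 and CELF6 at -0.024. EEF1D was then at -0.016, HMG20B at -0.144 and IGFBP2 at -0.189. Of the 31 called genes other than HTATSF1, 2 still passed without the filter and 13 moved by over 1.5 times. With the higher floor GRM4 was at 0.044, EEF1D at -0.274 and UXT at -0.153, and 21 of the 27 of these genes that had a value still passed. With the mean of the probe sets 17 of the 31 passed and 14 moved by over 1.5 times, among them CPNE7 (0.147), GRM4 (0.068), TRIML2 (0.055), EEF1D (-0.186), RAC3 (-0.203), HMG20B (-0.15), HDGF2 (-0.240), OGFR (-0.168), FKBP1A (-0.055), RBBP4 (-0.073) and UXT (-0.135).

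**Figure D2:**
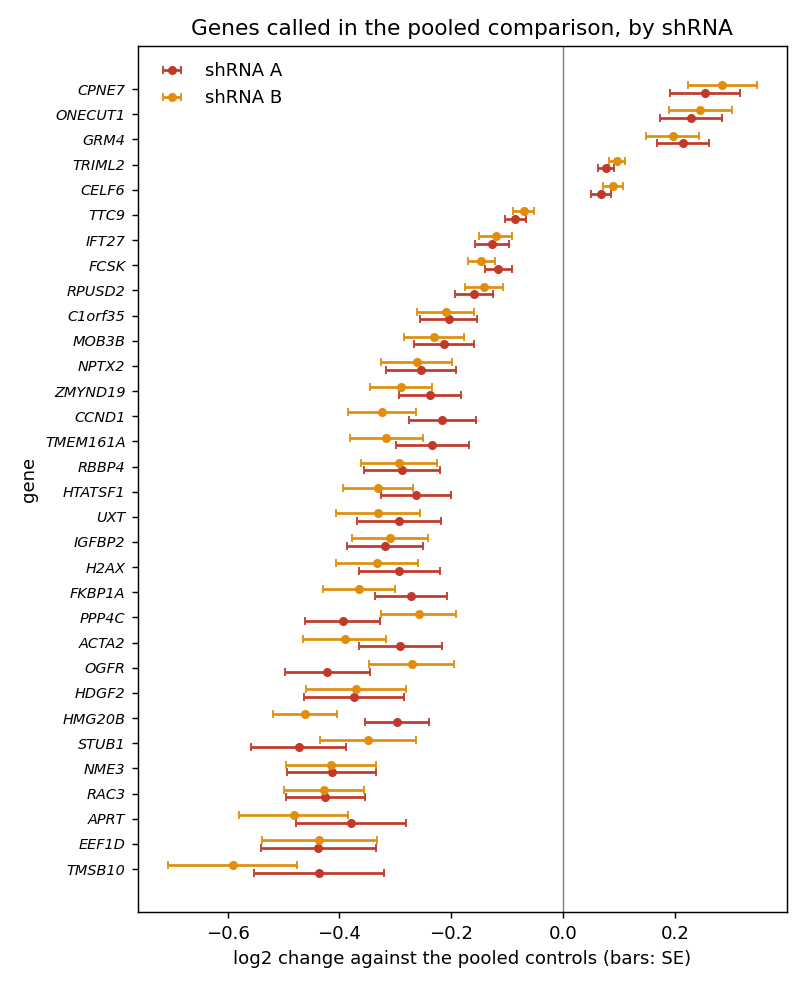
Log2 change of the 32 genes that passed in the pooled comparison (horizontal axis, against the 5 controls), shown for shRNA A and shRNA B, with the standard error as bars. TMSB10 lies at -0.44 for shRNA A and -0.59 for shRNA B, and CPNE7 at 0.25 and 0.28; the genes were chosen on both shRNAs together.

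Of the gene lists, 6 of 31 passed with camera, 5 toward lower and 1 toward higher values. Of 28 histone genes listed, 7 were measured, and all had lower means in the knockdown arrays, with a median of -0.308 (adjusted p = 0.00057, and adjusted p = 0.47 with an estimated correlation). H2AX was the member that passed over all genes, and 5 members fell when adjusted over the list alone. Of the 29 measured targets of ATF4, a transcription factor of the amino acid response, 25 had lower means (median -0.158, adjusted p = 0.00061, and adjusted p = 0.77 with an estimated correlation). No member passed over all genes and 11 fell when adjusted over the list alone, among them ATF4 itself (-0.40 ± 0.097, SE) and CEBPG (-0.34 ± 0.078, SE). Of the 48 cytosolic ribosomal protein genes, 41 had lower means (median -0.118, adjusted p = 0.0024, and adjusted p = 0.77 with an estimated correlation). None of these passed over all genes and 3 fell when adjusted over the list alone; RPS2 was at -0.32 ± 0.063 and RPL13 at -0.29 ± 0.074 (SE). Of 34 oxidative phosphorylation genes, 31 had lower means (median -0.073, adjusted p = 0.0029, and adjusted p = 0.72 with an estimated correlation), with none over all genes and 7 falls adjusted over the list alone, NDUFS7 at -0.40 ± 0.11 and SDHA at -0.31 ± 0.091 (SE). Of 37 genes of DNA replication and S phase, 32 had lower means (median -0.073, adjusted p = 0.013, and adjusted p = 0.77 with an estimated correlation), with none over all genes and 6 falls adjusted over the list alone. UHRF1, at -0.23 ± 0.072 (SE), was among these 6, and the licensing factor CDT1, at -0.31 ± 0.11 (SE), was not.

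Several of these members moved by over 1.5 times with the choice of probe sets. Without the filter on dim probe sets NDUFS7 was at -0.027, ATF4 at -0.159, CEBPG at -0.122, RPL13 at -0.132 and the histone gene H3-3A at 0.065 (-0.308 with the filter). SDHA was at -0.142 with the higher floor. With the mean of the probe sets NDUFS7 was at -0.201, SDHA at -0.106, ATF4 at -0.155, CEBPG at -0.215, RPS2 at -0.172 and H3-3A at -0.074.

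The list of interferon and double-stranded RNA response genes passed toward higher values (adjusted p = 0.044, and adjusted p = 0.51 with an estimated correlation), but its median change was 0.000 and its mean 0.004, with 15 of 29 members higher and 14 lower. None of its members passed, over all genes or adjusted over the list alone, and ADAR was at 0.06 ± 0.063 and IRF9 at 0.05 ± 0.032 (SE). No list passed with an estimated correlation. By fry, which tests whether a set moves one way without comparing it with other genes, 3 lists passed, all toward lower values: histone genes, p53 targets and oxidative phosphorylation. The control arrays were brighter than the knockdown arrays, as given above, and the falls of the lists went the same way. After quantile normalization the histone genes (median -0.239), ATF4 targets (-0.096) and ribosomal proteins (-0.060) still passed toward lower values, while the interferon list, oxidative phosphorylation and DNA replication did not pass and the small RNA processing list passed toward higher values (median 0.057, against 0.005 as deposited; this alternative was chosen after seeing the data). Without shRNA B replicate 2, 10 lists passed, and in other splits of the 11 arrays as many as 12 did.

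Genes of splicing, of transcription elongation and of the p53 response were examined as lists too. The list of the U2 snRNP and SF3 complexes also holds further splicing factors, such as U2AF1 and U2AF2. Of its 21 measured genes, 16 had lower means, and none passed over all genes or adjusted over the list alone (camera adjusted p = 0.74). SNRPA1 was at -0.24 ± 0.09 and U2AF2 at -0.18 ± 0.089 (SE). Of 36 other spliceosome genes, 4 fell when adjusted over the list alone and none over all genes, with SNRPA at -0.30 ± 0.074 and LSM4 at -0.25 ± 0.073 (SE; camera adjusted p = 0.27). Of 35 SR protein and hnRNP genes none passed on either basis (camera adjusted p = 0.74), and SRSF9 was at -0.24 ± 0.085 and HNRNPA3 at -0.21 ± 0.081 (SE). Of 35 transcription elongation factor genes, NELFB alone passed when adjusted over the list alone (-0.24 ± 0.061, SE), none passed over all genes, and TCEA2 was at -0.18 ± 0.073 (camera adjusted p = 0.27). The medians of the U2 snRNP (-0.062), other spliceosome (-0.048) and SR protein (-0.026) lists changed sign after quantile normalization, to 0.001, 0.014 and 0.027, and with cyclic loess they were -0.001, 0.010 and 0.022. Of 26 p53 targets, 20 had lower means and 4 fell when adjusted over the list alone, none over all genes (camera adjusted p = 0.063). Without the filter on dim probe sets U2AF2 was at -0.065 and NELFB at -0.121, and with the mean of the probe sets SNRPA1 was at -0.141, SNRPA at -0.199, SRSF9 at -0.132 and HNRNPA3 at -0.069. Of the p53 targets, GADD45A was at -0.26 ± 0.064 and TNFRSF10B at -0.25 ± 0.06 (SE). Markers of fibroblasts, endothelial cells, hepatocyte lines and carcinoma lines did not pass (camera adjusted p between 0.12 and 0.64), with mean control levels between 7.93 and 8.25, and 1 blood cell marker was measured.

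The series also asked for differential exon changes. Relative to its gene, 1 probe set rose, in SKIC3, a subunit of the complex that feeds RNA to the cytoplasmic exosome (0.42 ± 0.044, SE). In 6 genes a probe set fell relative to the rest of the gene. These were MARCKSL1 (-0.60 ± 0.065, SE), TMEM50A (-0.57 ± 0.055), the ubiquitin ligase ZNF598 (-0.43 ± 0.044), the bromodomain protein ATAD2 (-0.38 ± 0.038), PRELID3B (-0.35 ± 0.038) and the kinase VRK1 (-0.21 ± 0.023). The probe set of TMEM50A averaged 9.24 ± 0.042 (SD, n = 5) in the controls and 8.67 ± 0.15 (SD, n = 6) in the knockdown arrays, while its gene value differed by -0.01. That of MARCKSL1 went from 10.31 ± 0.065 to 9.78 ± 0.16, in a gene measured by 4 probe sets. That of SKIC3 went from 10.02 ± 0.11 to 10.39 ± 0.13, and that of ZNF598 went from 8.23 ± 0.12 to 7.69 ± 0.087, below the level of dim probe sets.

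These 7 of 221964 probe sets all had an adjusted p of 0.0382. Each had the same sign with both shRNAs. That sign is no separate evidence, since the probe sets were chosen on both shRNAs together and their groups did not overlap. None lay in the 32 genes whose own level changed. Unadjusted, 26097 probe sets had a p under 0.05, 2.35 times the 11098 given by chance. The count was 0 without any 1 of shRNA A replicate 3, shRNA B replicate 2, GFP shRNA replicates 2 and 3 or either empty vector array. Where limma gave 0, between 22813 and 24816 probe sets had an unadjusted p under 0.05. Without shRNA A replicate 1 the count was 2 (1 of them among the 7), and without shRNA A replicate 2 it was 1 (1 shared). It was 1 (0 shared) without shRNA B replicate 3 and 4 (2 shared) without shRNA B replicate 1. Without GFP shRNA replicate 1 it was 95 (7 shared). With the array-name suffix as a block no probe set passed by limma (16385 at an unadjusted p under 0.05), and diffSplice called 2966.

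Each shRNA was also set against the pooled controls. With shRNA A only CEBPE, a transcription factor of myeloid cells, fell (-0.58 ± 0.076, SE; adjusted p = 0.0203), from a control mean of 8.60 to 8.02 ± 0.084 (SD, n = 3). With shRNA B 6 genes fell, among them ZNF580 (-0.61), ATF4 (-0.57), PTOV1 (-0.54), HMG20B (-0.46) and RAC3 (-0.43), and 4 rose, TMEM191A (0.57), SPTBN5 (0.23), TRIML2 (0.10) and C9orf43 (0.09). ATF4 averaged 9.74 ± 0.131 (SD, n = 3) with shRNA B and 10.07 ± 0.113 (SD, n = 3) with shRNA A, against 10.31 in the controls. Of the 10 genes of shRNA B, 4 were also among the 32 of the pooled comparison, which shares its arrays, against 0.022 for independent lists; the calls of shRNA A and shRNA B shared 0 genes. At an unadjusted p under 0.05 there were 1566 genes for shRNA A and 1929 for shRNA B. All 3 arrays of shRNA B and none of the 5 controls had the suffix in their names, so for shRNA B the suffix and the shRNA cannot be told apart.

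The CEBPE call was lost without shRNA A replicates 1 or 3 or GFP shRNA replicates 2 or 3 (0 genes each by limma, with 1233 to 1610 at an unadjusted p under 0.05), the 2 genes that passed without shRNA A replicate 2 did not include it, and 0 passed by limma after quantile normalization (1395) or in the arrays without the suffix alone (1186). The 3 genes that passed with the higher floor did not include CEBPE either. CEBPE still passed without the filter on dim probe sets, without a trend and with the mean of the probe sets. For shRNA B the count by limma was 0 (1318 at an unadjusted p under 0.05), 2 and 3 without its replicates 1, 2 and 3, 5 without shRNA A replicate 3, 3 and 5 without GFP shRNA replicates 2 and 3, 4 without empty vector replicate 1, and 4 after quantile normalization. None of the 10 genes was among the 1 that passed without the filter on dim probe sets or the 14 that passed with the mean of the probe sets. Without the filter TMEM191A was at 0.020, SPTBN5 at 0.027, TRIML2 at 0.008, C9orf43 at 0.007, ZNF580 at -0.017, ATF4 at -0.244 and HMG20B at -0.170 for shRNA B. With the mean of the probe sets SPTBN5 was at 0.15, TRIML2 at 0.037, C9orf43 at 0.034, ATF4 at -0.177, PTOV1 at -0.329, HMG20B at -0.169 and RAC3 at -0.244, and C9orf43 was at 0.048 with the higher floor.

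No gene differed between shRNA B and shRNA A by limma (638 at an unadjusted p under 0.05, against 729 by chance; smallest adjusted p = 0.291). HTATSF1 differed by -0.07 ± 0.07 (SE) between them. The difference of ATF4 between them therefore did not pass, and neither did that of CEBPE. The 4 arrays with the suffix hold 1 array of shRNA A against 3 of shRNA B, so the 5 genes that passed in them rest on a lone array, assumed to vary like the others, and without shRNA A replicate 2 over all arrays 1 passed. Across genes, which are not independent replicates, the log2 changes of both shRNAs had a Pearson correlation of 0.644 and a covariance of 0.00389. Unchanged groups simulated against the same controls gave 0.376 and 0.00133, a difference of covariance of 0.00256. With split controls the correlation was 0.444 (covariance 0.00315) and 0.318 (covariance 0.00244). In 100 random relabellings of the 11 arrays it lay between -0.06 and 0.716, with a median of 0.41, and 3 reached the observed value.

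Between the 2 controls, LRP1B was lower with the GFP shRNA than with the empty vector (-0.11 ± 0.014, SE; adjusted p = 0.0198), at a mean of 7.94 against 8.05, near the level of dim probe sets. It was the only gene to pass (648 at an unadjusted p under 0.05), with 2 empty vector arrays. The call was kept without GFP shRNA replicate 3 and lost without any other array: without empty vector replicate 1, where the remaining one is assumed to vary like the other groups, the 2 genes that passed did not include LRP1B, and without each of the others limma called 0 genes (518 to 888 at an unadjusted p under 0.05).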

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

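The tests on brightness, gene size and the probe set without a gene were chosen after their results had been seen; the splits of the arrays and both tests on the suffix were set before, the second of them after the first.

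In 1 of 100 splits of the 11 arrays, the real one, as many as 32 genes passed, and the highest other split called 1, so chance is unlikely for that count. For exon usage the real split gave 7 probe sets and the highest other gave 2 (1 of 100 splits as large), so chance is unlikely there too. That count was 0, however, when any 1 of 6 arrays was left out. For both counts the splits cannot tell the knockdown from the brightness of the arrays or from the suffix, which most knockdown arrays and no control carry. For gene lists, 14 of 100 splits called as many as the real 6, up to 12, and chance cannot be excluded. Among the 56 splits of the control and shRNA B arrays only the real one called 10 genes and the highest other called 1, so chance is unlikely. The suffix cannot be excluded, since all 3 shRNA B arrays and no control carry it. Among those for shRNA A, 3 of 56 called at least the real count of 1, up to 2, and chance cannot be excluded. For shRNA B against shRNA A all 10 splits called at least the real count of 0, up to 1, and 10 splits are too few for a share under 0.05.

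Falls outnumbered rises among the 32 genes, and the control arrays were brighter. After quantile normalization 37.5% of the called genes were falls (3 of 8, with 2 of the 5 rises newly called), so the brightness of the arrays may account for the excess of falls. That share rests on 8 genes, and a scaling that gives every array the same distribution can itself shift the balance of rises and falls. The median of the 27 falls, HTATSF1 included, went from -0.313 (SD 0.106) to -0.252 (SD 0.087) with this scaling. All 27 stayed below 0 at an unadjusted limma p under 0.05, and 3 still passed, with a median SE of 0.054 against 0.055. The 27 genes were chosen on these same arrays, so these values cannot show how much of their fall the brightness accounts for. The suffix stays open. In the arrays without it shRNA A gave a median of -0.26 (SD 0.105) for these genes, but they were chosen on the same arrays, so that the bound set for this test was wrong. Another set of 27 falls was chosen on the 4 arrays with the suffix and the 3 GFP shRNA arrays (11 of them among the called ones). In the 2 other shRNA A arrays against the 2 empty vector arrays this set had a median of -0.17 (SD 0.168, 24 below 0), against -0.009 for all genes. The median was within that SD of the bound of -0.1, but the SD is a spread over genes and not an error of the median. This set thus went lower where no array had the suffix, but with 2 arrays per group. The part of the suffix in the called falls was not measured. Also open are Tat-SF1 depletion itself and a bias toward small genes, since the 27 had a median of 12 probe sets on the array against 19 for random sets of the same level (percentile 0.04), although over all genes the change hardly followed the number of probe sets (Spearman 0.017).

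Of the probe sets that the annotation does not list with a gene, 460199 were tested, and 2 of these differed between the groups. Probe set 3555331 lay between 7.87 and 7.93 in the 5 controls and averaged 9.66 ± 0.054 (SD, n = 6) in the knockdown arrays, a log2 difference of 1.76 (limma adjusted p = 1.04e-07). Its controls are at the median level of the arrays, and if that level is background, the difference is a lower bound for the change of the transcript. It was high with shRNA A (9.69) and shRNA B (9.63), and among the shRNA A arrays both without the suffix (9.70 and 9.66) and with it (9.70). The other, 3024276, rose by 0.14 (adjusted p = 0.035), near the level of dim probe sets. The next number after the first, 3555332, was too dim to be tested among these: it averaged 4.56 ± 0.99 (SD, n = 5) in the controls, with 5.63 for the empty vector and 3.85 for the GFP shRNA, and 6.86 ± 0.3 (SD, n = 6) in the knockdown arrays (exact permutation p = 0.0022), both below the level of dim probe sets. Both probe sets that passed are signals in data that the comparisons of the report do not use.

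The 2 probe set numbers before 3555331 belong to RPPH1, the RNA of ribonuclease P, whose promoter is widely used to express shRNAs. Read-through from RPPH1 stays open and cannot be told apart from the other sources, since its probe sets averaged -0.298 without a difference beyond the spread between arrays (exact permutation p = 0.49 and 0.25) and a small share of read-through need not raise them. RNA from vector parts that all constructs share is argued against because every control array, GFP shRNA included, lay within 0.03 of its median level. RNA made from the Tat-SF1 shRNA constructs themselves may be the source, since the lowest knockdown array lay 1.62 above the highest control, but no vector sequence was used here, and it cannot be told apart from a response of the cells to the depletion, which was not tested.

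Single arrays stood apart in 6 of 136 groups of arrays tested, where chance gives about 6.8. C1orf35 was at 8.50 in GFP shRNA replicate 1 against a mean of 8.30 in the other controls. CEBPG was at 10.20 in the same array against 9.84. The splicing index of the ATAD2 probe set was 0.34 there against 0.44. That of TMEM50A was -0.32 in shRNA A replicate 2 against -0.62 in the other knockdown arrays. That of SKIC3 was 1.23 in shRNA A replicate 1 against 1.40. Probe set 3555331 was at 9.56 in shRNA B replicate 2 against 9.68.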

How the results depend on the processing

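The alternatives with cyclic loess, a background-subtracted scale or without the 2 arrays at the ends of the first component, quantile normalization for exon usage, lists and the correlation, and the trend on the probe set level were chosen after seeing the data. The 32 genes became 19 (2 shared) without a filter, 130 (22 shared) with the floor at the upper quartile, 8 (6 shared) with quantile normalization, 7 (5 shared) with cyclic loess, 89 without a trend, 137 with the mean of probe sets, 15 with 4 constructs as levels, 279 with the construct as a random block (its estimated correlation was -0.086), 2 with the GFP shRNA controls alone, and 0 with the suffix block, at 1.5-fold, or without the 2 end arrays. Leaving out each array gave 2 to 47. The suffix block leaves fewer arrays to the contrast, since all controls and no shRNA B array lack the suffix. The random block, with its negative correlation, came with smaller SEs, as for HTATSF1 (0.051 to 0.047) and RAC3 (0.057 to 0.051), so its higher count is not stronger evidence. For the other settings the cause was not tested. HTATSF1 stayed lower throughout, but did not pass without a filter (-0.252), with quantile normalization (-0.256), cyclic loess (-0.257), the suffix block (-0.254) or without the end arrays (-0.270), and leaving out each array gave -0.343 to -0.265. For shRNA A the 1 gene became 9 (1 shared) without a filter, 3 (0 shared) with the higher floor and 0 with quantile normalization. It became 10 (1 shared) without a trend, 14 (1 shared) with the mean, 0 in the arrays without the suffix, and 0 to 2 without single arrays. For shRNA B the 10 genes became 1 (0 shared), 29 (5 shared) and 4 (4 shared) with the first 3 of these settings, 14 (0 shared) with the mean and 1 with the GFP shRNA controls alone, and 0 to 9 without single arrays. Between the shRNAs 3 genes passed with the higher floor, 5 in the arrays with the suffix (1 array of shRNA A against 3 of shRNA B), and 0 to 1 without single arrays. The 1 gene between the controls became 0 without a filter, with the higher floor and without a trend, and 0 to 2 without single arrays. The 7 probe sets became 19 (5 shared) with the higher floor, 2 (1 shared) with the mean and 2966 (4 shared) with diffSplice. They became 893 (7 shared) with the random block, 0 with the suffix block and 1 (1 shared) at 1.5-fold. The count was 1 (1 shared) with the trend on the probe set level, 4 (1 shared) without the end arrays, and 0 to 95 without single arrays. The 6 lists became 0 with an estimated correlation and 11 with the mean, and 4 to 10 without single arrays. The correlation of 0.644 became 0.444 and 0.318 with split controls and 0.587 with quantile normalization, and 0.578 to 0.679 without single arrays. Signs turned without a filter for ONECUT1 (-0.009), CELF6 (-0.024), SNRPD3 (-0.085) and H3-3A (0.065), and with the mean for IFI6 (-0.006); the cause was not tested. Among 85 single gene results, 642 values no longer passed, 1290 kept their direction and side of the threshold and 30 newly passed. The replicate numbers gave no clear pairing of the arrays: of 15 same-numbered pairs 5 correlated over 0.1 (range -0.148 to 0.269), and 4 of 11 arrays correlated best with their own number. A partial pairing is not excluded. With a replicate block 10 genes passed (8 shared), HTATSF1 was at -0.297 with an adjusted p of 0.0604, shRNA B gave 4 genes, the controls 0 and exon usage 0 probe sets. The background-subtracted scale, which takes the median level of an array as background, gave -0.951 for HTATSF1 and 25 genes (23 shared).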

Other observations

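The test of diffSplice was set before its result was seen, and the look at brightness in the splits came after. For exon usage, diffSplice, which shares 1 variance among the probe sets of a gene, called 2966 probe sets where the splicing index called 7, and 4 were called by both. In 19 other splits of the 11 arrays diffSplice called between 86 and 1615 probe sets, with a median of 439. A count as high as 1615 in another split may come from the shared variance, so the 2966 are not counted as changes here. How far that split mixed the groups was not recorded, and the shared variance was not tested apart from group differences left in it. None of those 19 splits reached 2966, so a part of the excess may reflect differences in exon usage too small for the splicing index at this number of arrays. In 100 splits, the 26097 probe sets with an unadjusted p under 0.05 by the splicing index were the most, with 22486 in the highest other split and a median of 11009. For gene values the same count was 2216 in the real split, with a median of 629 in the others, and 2151 in the highest other split. The 5 other splits with the highest counts (2151, 2123, 1880, 1845 and 1821) parted the arrays by brightness, with differences of -0.054, 0.058, 0.077, 0.060 and -0.066 between their groups against -0.067 in the real split. Other splits with like differences (0.068, 0.061 and -0.062) gave lower counts, of 1136, 1324 and 1281. So did those with differences of 0.058, 0.057, -0.057, -0.055 and 0.054, with counts of 998, 902, 1459, 1026 and 828. The counts may thus go with the brightness of the arrays as well as with the groups, but brightness alone did not set them.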
